A study of Homo sapiens with 75 samples.

How the data were processed

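Total RNA of 75 samples of human mantle cell lymphoma lines was labelled by the authors as biotinylated cRNA and hybridized to 1 Affymetrix 3' expression array each. The 5 lines and 5 treatments make 25 groups of 3 replicates. The labels give a line, a treatment and a replicate number for each array and a concentration of 10 µg/ml for each antibody, and nothing on treatment time, scan dates or batches. The deposited values are intensity on a linear scale, which the authors scaled to the same mean on every array. The submitters' processing notes name MAS5; its version, its settings and any background step are not given in the sources used here. That the values are linear, at least 0 and equally scaled was checked on the file. Per array, the median intensity was 11.06 to 17.42, the highest 8699 to 11666, and 4.08% to 8.87% of probe sets were at 0. Replicates of a group correlated at r = 0.9634 to 0.9734. The log2 ratio of 3' to 5' probe sets was -0.052 to 0.201 for GAPDH and 0.616 to 1.325 for actin. Raw image files were not analysed here.

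Of 54675 probe sets, 62 controls were left out, a choice that was not planned. The platform's annotation gave 1 gene symbol to 41097 probe sets, several to 1801 and none to 11777. Those with several or none were not used. Of the 41091 with 1 symbol that were not controls, 41037 matched a current gene by Entrez identifier and 0 symbols changed. They stood for 19775 genes. Values under 1 were set to 1 and log2 transformed, with no further normalization. A probe set stayed if its mean log2 value over the 15 arrays of at least 1 line was above the median of all probe sets (log2 3.55, intensity 11.7); 32926 stayed. The probe set with the highest mean stood for its gene, which left 13870 genes. Among 225 pairs of a named gene and a comparison, 84 had another probe set past the filter, and in 31 it had the opposite sign.

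limma fitted 25 group means to the 75 arrays (50 residual degrees of freedom; median prior degrees of freedom 5.83), with empirical Bayes moderation and an intensity trend, and p-values were adjusted by Benjamini and Hochberg over all genes within each comparison at a threshold of 0.05, all two-sided. In each line GA101, rituximab and the combination were compared with isotype, GA101 with rituximab, and isotype with PBS. Over all lines, with equal weight for each line, the same comparisons were made, as were the combination against each antibody and the departure of the combined change from the sum of the single changes. Moderated F tests with 4 numerator degrees of freedom asked whether the response to GA101 or to rituximab against isotype differed between the 5 lines. The REC-1 minus JEKO-1 difference of the GA101 response was tested in the same model, for a pair and a list chosen after their values were seen. The position of the combination was the slope through the origin of combination minus rituximab on GA101 minus rituximab.

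Gene lists were tested with camera (preset correlation 0.01), with camera with an estimated correlation and with fry, for the 23 of 25 lists with at least 5 tested genes, adjusted over lists. Counts of members are also given adjusted over the list alone. The lists were B cell receptor signalling, immediate early genes, NF-kB targets, pro-apoptotic and anti-apoptotic BCL2 families, p53 targets, G1/S and DNA replication, G2/M and mitosis, MYC targets and ribosome biogenesis, cholesterol biosynthesis and SREBP targets, interferon response, ER stress and ATF4 targets, heat shock, lysosome and autophagy, actin cytoskeleton and adhesion, MHC class II, hypoxia and glycolysis, NRF2 targets, chemokines with cytokines and their receptors, complement regulators and Fc receptors, mantle cell lymphoma markers, and markers of T cells, of epithelial cells and fibroblasts, of myeloid and of erythroid cells. Some genes stand in more than 1 list. BCL2A1 and CFLAR are in the NF-kB and the anti-apoptotic list. The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be added later.

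The rule named MS4A1 and CCND1 always. Over all lines it named the 10 largest rises and the 10 largest falls past 0.05 with the same sign in all 5 lines, for the 3 comparisons against isotype and for GA101 against rituximab. In each line it named the 4 largest rises and 4 largest falls past 0.05 whose 3 and 3 arrays do not overlap, for GA101 and rituximab against isotype and GA101 against rituximab. For other comparisons it named the 5 genes with the smallest adjusted p, and of each list described up to 4 members with the largest change and any opposing member past 0.05. For the single lines, giving only those of the 8 genes that passed without each array and, where isotype was the control, against PBS was decided after the data were seen.

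Other ways of fitting, chosen in advance, were a block for the replicate number, quantile normalization, no filter, the mean of a gene's probe sets, array weights by line for results over all lines and a separate fit for each line, an offset of 3.69 (the 25th percentile) before the logarithm, PBS in place of isotype, an estimated correlation for lists, and leaving out each array. Where leaving out an array left 2 in a group, the fit pooled the spread over groups. Added after seeing the data were a stricter filter at the 75th percentile (intensity 67.5, 9233 genes), counts of genes passing in the same direction against both controls, and PBS in place of isotype for the departure from the sum, its gene lists included. Other splits of the arrays into groups of the same size were run for each count. The overlap of comparisons that share the isotype arrays was set against 20 simulations with no effect.

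The calls were tested on simulated data with the observed spread and 13870 genes. Where no gene differed, at most 2 genes were called in any of 35 comparisons. With 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale, the Z138 comparison recovered 49.3%, 53.7% and 87.9% of them, with 9 of 136 calls false (6.62%). The comparison over all lines recovered 67.2%, 82.1% and 100%, with 9 of 175 calls false (5.14%), and the F test 38.8%, 49.3% and 81.8%, with 7 of 120 false (5.83%). A shift of 0.3 put into the NF-kB list was found by camera (adjusted p = 2.6e-66), along with 1 other list that shares genes with it. R 4.3.3, limma 3.58.1 and version 1.17.8 of the data.table package were used, and Python 3.11.15 with matplotlib 3.10.9 for plots.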

Results

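Transcript levels were measured on 75 arrays in 5 established mantle cell lymphoma lines, Z138, GRANTA-519, HBL-2, JEKO-1 and REC-1, which grow from a B cell lymphoma that usually carries a cyclin D1 translocation. Each line was given 5 treatments with 3 replicate arrays each: GA101, rituximab, both together, an isotype control antibody, or PBS. GA101 is obinutuzumab, a glycoengineered antibody against CD20. Rituximab is an older antibody against the same B cell surface protein, and each was used at 10 µg/ml. The labels give no treatment time. The series title asks how antibodies against CD20 regulate genes in this lymphoma. Mean intensity was the same on every array, and the median intensity over probe sets ranged from 11.06 to 17.42. The number of arrays limits the precision: changes are log2 fold changes ± standard error, with 15 arrays per arm over all lines and 3 per group within a line. The p-values measure the spread between arrays, which may be technical, since the labels do not say that replicates were separate cultures.

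MS4A1 is the gene of CD20. Its intensity over the 6 control arrays was 5860 ± 429 in Z138, 6390 ± 150 in GRANTA-519, 4290 ± 136 in HBL-2, 5010 ± 232 in JEKO-1 and 6040 ± 233 in REC-1 (SD, n = 6). Over all lines MS4A1 changed by 0.03 ± 0.0237 after GA101 (adjusted p = 0.48), 0.07 after rituximab (adjusted p = 0.019) and 0.07 after both (adjusted p = 0.028). Against PBS the last pair of values were 0.04 and 0.04 and did not pass (adjusted p = 0.3 and 0.38). The rituximab call ended without Z138 isotype replicate 1 (0.06, adjusted p = 0.052). That of both antibodies ended there (0.073) and without Z138 combination replicate 2 (0.07), GRANTA-519 combination replicate 1 (0.067), HBL-2 isotype replicate 3 (0.055), JEKO-1 combination replicate 1 (0.081) or JEKO-1 isotype replicate 2 (0.068). CCND1, the gene of cyclin D1, changed by -0.10 ± 0.0999, -0.09 and -0.09 in the same comparisons (adjusted p = 0.57, 0.62 and 0.62).

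The isotype control arm was compared with PBS to learn what background the other comparisons carry. Mitotic genes were lower with the isotype control: of 25 tested G2/M genes, 0 were higher, 21 lower and 4 not called (0 and 22 adjusted over the list alone). CENPE, a kinetochore motor, was at -0.38, HMMR at -0.36 and the kinase AURKA at -0.32. This list was lower than other genes (adjusted p = 1.8e-49, or 1.2e-10 with an estimated correlation). Heat shock genes were lower too, 3 of 9, with HSPH1 at -0.22 (adjusted p = 0.00036, or 0.033 with an estimated correlation). Of 18 hypoxia and glycolysis genes 4 were lower, among them ADM at -0.47 and DDIT4 at -0.40. Of 25 G1/S genes 4 were higher, among them CDC6 at 0.21 and CCNE2 at 0.20. Both of these lists passed (adjusted p = 0.032 and 0.0014) and lost the call with an estimated correlation (adjusted p = 0.27 and 0.1). The 5 genes with the smallest p were PHF14 at -0.71 ± 0.026, the HSP90 partner CHORDC1 at -0.68 ± 0.0308, the centromere protein CENPF at -0.32 ± 0.0205, TIMM17A at -0.28 ± 0.0208 and TXNIP at -0.63 ± 0.0479. The mean of the probe sets of PHF14 changed by 0.03. In all, 896 of 13870 genes differed between the control arms, 642 with the same sign in all 5 lines. With the isotype antibody 300 were higher and 596 lower. For this reason counts of all genes called against isotype are followed by counts against PBS, and lists described as passing by a result against PBS, and GA101 against rituximab, which uses no control arm, is free of this shift.

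GA101 against isotype over all lines asked which genes the antibody changed. Immediate early genes, the first genes transcribed after receptor signals, rose: 12 of 22 were higher, 0 lower and 10 not called (13 and 0 adjusted over the list alone). Examples were the zinc finger factors EGR3 at 1.60 ± 0.095 and EGR1 at 1.49 ± 0.0673. EGR1 intensity was 704 with GA101 and 180 with isotype. The list rose (adjusted p = 3.3e-14, or 1.3e-07 with an estimated correlation), and against PBS 14 were higher and 1 lower. NF-kB targets rose as well, with 9 of 20 higher and 0 lower (10 and 1 adjusted over the list alone; adjusted p = 0.00011, or 0.0027 with an estimated correlation). Among them were the chemokine CCL4 at 1.34 ± 0.063, the NF-kB inhibitor NFKBIE at 0.35 ± 0.051, the maturation marker CD83 at 0.35 ± 0.031 and the caspase 8 regulator CFLAR at 0.35 ± 0.034; 6 were higher and 0 lower against PBS. G2/M genes were higher than with isotype, 21 of 25 and 0 lower (22 and 0 adjusted over the list alone), for example the spindle factor TPX2 at 0.39 ± 0.038 and CDC20 at 0.34 ± 0.029 (adjusted p = 9.5e-21, or 5.5e-06 with an estimated correlation). Against PBS only 1 G2/M gene was higher and 4 were lower (adjusted p = 0.053), and the list's median was -0.017. This mean hides lines that went apart. Against PBS 15 were lower and 0 higher in REC-1 (adjusted p = 1e-13, or 2e-04 with an estimated correlation). In HBL-2 3 were higher and 0 lower (adjusted p = 5.5e-05, or 0.063 with an estimated correlation). G1/S genes fell, 8 lower and 2 higher of 25 (9 and 2 adjusted over the list alone), with CCNE2 at -0.27, CDT1 at -0.20 and PCNA at -0.17, while MCM5 at 0.16, whose call ended in 18 of 30 fits without 1 array, and GINS1 at 0.13 rose (adjusted p = 0.00031, or 0.047 with an estimated correlation). Against PBS 1 was lower and 2 higher (adjusted p = 0.29).

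Of 4 more lists that passed with a preset correlation, all lost the call with an estimated one. Heat shock genes had 3 of 9 higher and 0 lower (4 and 0 adjusted over the list alone), with the chaperone HSPH1 at 0.40 ± 0.021 (adjusted p = 0.0067, or 0.094 with an estimated correlation). Lysosome and autophagy genes had 7 of 18 higher and 0 lower (7 and 0 adjusted over the list alone), with the protease CTSA at 0.32 ± 0.058 and the autophagy receptor SQSTM1 at 0.25 (adjusted p = 0.046, or 0.32 with an estimated correlation). The call of SQSTM1 ended with the mean of its probe sets. Hypoxia and glycolysis genes had 5 of 18 higher and 1 lower (6 and 1 adjusted over the list alone), with ADM at 0.58 and the opposing PGK1 at -0.05, whose call ended in 15 fits without 1 array (adjusted p = 0.017, or 0.16 with an estimated correlation). Chemokines, cytokines and their receptors had 6 of 19 higher and 0 lower (6 and 0 adjusted over the list alone), with TNFSF9 at 0.34 (adjusted p = 0.046, or 0.17 with an estimated correlation). Against PBS the lysosome list passed (adjusted p = 0.015, or 0.27 with an estimated correlation) and the heat shock, hypoxia and chemokine lists did not (adjusted p = 0.75, 0.73 and 0.069). There 4 lysosome, 1 heat shock, 1 hypoxia and 4 chemokine genes were higher and 0 lower, and ADM changed by 0.12. By line (preset correlation) the lysosome and chemokine lists passed in HBL-2 only and the hypoxia list in GRANTA-519 only. NF-kB targets also passed upward in Z138, REC-1 and HBL-2 (downward against PBS) and downward in JEKO-1. Without 1 array the lysosome call was lost in 16 of 30 fits (adjusted p up to 0.1) and the chemokine call in 15 of 30 (adjusted p up to 0.093).

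The other lists did not pass against isotype after GA101. Members higher and lower were 6 and 1 of 21 for B cell receptor signalling (adjusted p = 0.74), 2 and 0 of 9 for the pro-apoptotic BCL2 family (0.84), 3 and 1 of 8 for the anti-apoptotic family (0.3), 2 and 0 of 18 for p53 targets (0.95) and 4 and 4 of 17 for MYC targets and ribosome biogenesis (0.84). They were 0 and 4 of 18 for cholesterol biosynthesis (0.18), 2 and 0 of 20 for the interferon response (0.3), 4 and 1 of 20 for ER stress and ATF4 targets (0.24), 6 and 0 of 20 for actin cytoskeleton and adhesion (0.18) and 1 and 0 of 12 for MHC class II (0.84). They were 2 and 1 of 11 for NRF2 targets (0.84), 0 and 1 of 10 for complement regulators and Fc receptors (0.84), 0 and 0 of 6 for mantle cell lymphoma markers (0.95), 0 and 0 of 7 for T cell markers (0.93) and 0 and 0 of 5 for epithelial and fibroblast markers (0.8). Against PBS actin cytoskeleton and adhesion passed, with 6 higher and 0 lower (adjusted p = 0.027, or 0.27 with an estimated correlation), and the other 14 did not (adjusted p of 0.25 or more). Myeloid and erythroid markers had fewer than 5 tested genes and were not tested. The median, the mean and the test differed in sign for the B cell receptor, MYC, cholesterol, MHC, NRF2, complement, T cell and mantle cell lymphoma lists.

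Over all lines GA101 called 2529 genes, 1728 higher and 801 lower than isotype. The sign was the same in all 5 lines for 1268 of them. The test uses the spread between arrays and not between lines, so a call can rest on few lines. After quantile normalization the split was 1241 and 1082. Against PBS 1469 genes were called, and 980 passed in the same direction against both controls. Of the 20 genes named for the largest changes shared in sign by all lines, MAFF, EGR1 and RNA45SN5 passed against PBS and without each array in turn. The small MAF factor MAFF rose by 1.58 ± 0.151, a size that depends on background and floor, since its weaker arm had a mean intensity under 11.7, the median probe set, in 3 lines (1.91 in Z138, 3.05 in JEKO-1 and 6.36 in REC-1). EGR1 was above that level in each line, and so was the ribosomal RNA gene RNA45SN5, which rose by 1.13 ± 0.0522. The latter has near-identical copies, so its identity is uncertain. The other 17, which did not pass one of these checks, were SLC33A2 at 1.26, the histone gene H3C8 at 1.23, with near-identical copies as well, PYCR3 at 1.22, CD34, TWF2-DT, SLC4A2 and ME3 among the rises. Among the falls they were SPMIP1 at -1.19, COL4A4 at -1.15, ADCY1 at -1.12, LINC01741, LINC00856, LOC400627, RIMS4, SEPTIN7P13, DNAJB13 and CRMA. Against PBS SPMIP1 changed by 0.37 and RIMS4 by 0.03, and mean intensities of SPMIP1 were 9.54 and 15, close to the median probe set at 11.7.

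**Figure D1:**
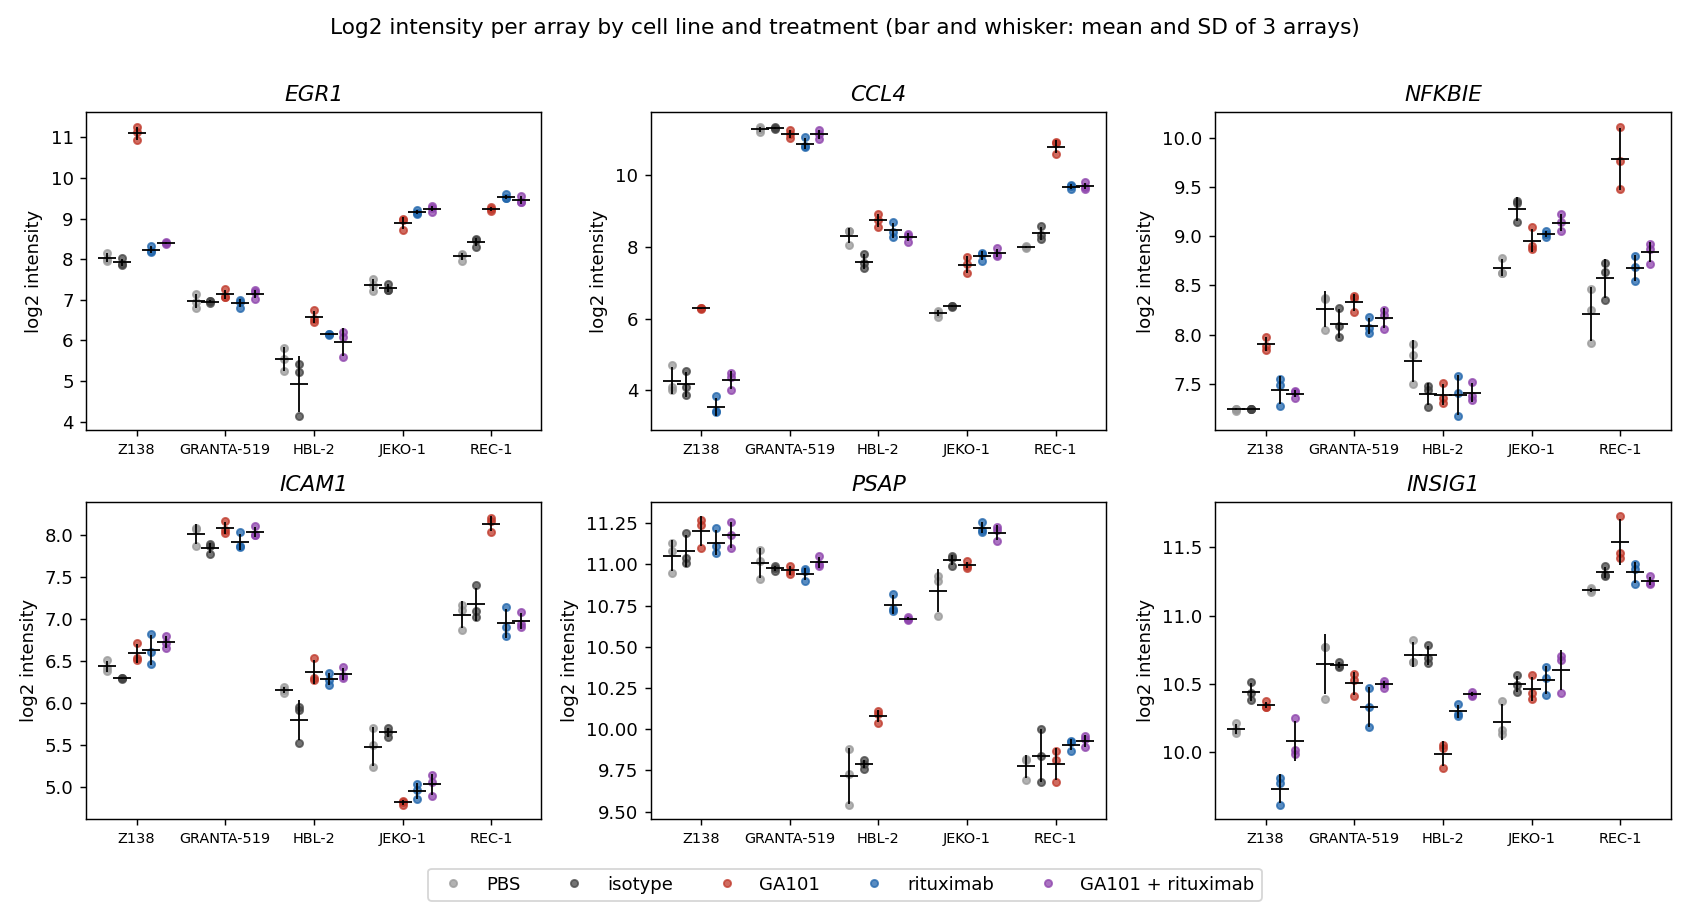
Intensity (log2 axis) of EGR1, CCL4, NFKBIE, ICAM1, PSAP and INSIG1 on each array by cell line and treatment, with the mean and SD of the 3 arrays of each group. EGR1 averaged 704 over the GA101 arrays of all lines and 180 over the isotype arrays. In Z138 alone these means were 2200 and 242.

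Rituximab against isotype asked the same of the other antibody. Immediate early genes rose, with 9 of 22 higher, 1 lower and 12 not called (10 and 1 adjusted over the list alone; adjusted p = 0.0019, or 0.022 with an estimated correlation). EGR1 rose by 0.90 ± 0.067 and EGR3 by 0.75, while IER5 fell by 0.11. Against PBS 9 were higher and 1 lower. Heat shock genes rose, 5 of 9 and 0 lower (5 and 0 adjusted over the list alone), with the HSP70 partner BAG3 at 0.55 and HSPH1 at 0.51 ± 0.021 (adjusted p = 0.00025, or 0.022 with an estimated correlation; against PBS 2 higher, 0 lower, adjusted p = 0.027). Lysosome and autophagy genes had 12 of 18 higher and 1 lower (12 and 1 adjusted over the list alone), with CTSA at 0.54 ± 0.058, the cholesterol exporter NPC1 at 0.26 and the saposin precursor PSAP at 0.25 ± 0.028. TFEB, a factor that drives lysosomal genes, fell by 0.31 (adjusted p = 0.00063, or 0.055 with an estimated correlation). Against PBS 8 of them were higher and 1 lower (adjusted p = 1.7e-05, or 0.016 with an estimated correlation). Cholesterol biosynthesis and SREBP target genes had 6 of 18 lower and 1 higher (8 and 1 adjusted over the list alone), with INSIG1 at -0.28, MVK at -0.21 and SQLE at -0.17 (adjusted p = 0.01, or 0.1 with an estimated correlation). Against PBS 3 were lower and 0 higher (adjusted p = 0.32). LSS rose by 0.11; its call ended without HBL-2 isotype replicate 3 (0.09, adjusted p = 0.053), and the mean of its probe sets changed by -0.01. With the mean of a gene's probe sets the calls of NPC1 and SQLE ended. Within single lines, with the preset correlation, the lysosome list passed in HBL-2 alone (adjusted p = 0.48, 0.95, 0.066 and 0.74 in Z138, GRANTA-519, JEKO-1 and REC-1), the immediate early list in JEKO-1 alone and the cholesterol list in Z138 alone.

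Mitotic genes were again above isotype after rituximab, 20 of 25 and 0 lower (24 and 0 adjusted over the list alone; adjusted p = 3.8e-21, or 8.9e-06 with an estimated correlation), with TPX2 at 0.41 and CDC20 at 0.39. Against PBS 4 were higher and 3 lower (adjusted p = 0.77), with a median of -0.012. G1/S genes had 8 of 25 lower and 1 higher (9 and 1 adjusted over the list alone), with CCNE2 at -0.38 (adjusted p = 0.00063, or 0.055 with an estimated correlation). Against PBS 3 were lower and 1 higher (adjusted p = 0.32). NF-kB targets had 2 of 20 higher and 5 lower (2 and 6 adjusted over the list alone) and did not pass against isotype (adjusted p = 0.099). Against PBS they were lower (adjusted p = 0.00069, or 0.012 with an estimated correlation). Rituximab called 2866 genes, 1909 higher and 957 lower, and 1558 of these had the same sign in all 5 lines. The split was 1553 and 1232 after quantile normalization, 1682 genes were called against PBS and 1292 passed in the same direction against both controls. Of the 20 genes named for the largest shared changes, H3C8 at 1.57 ± 0.396, RNA45SN5 at 1.49 ± 0.0522, MAFF at 1.46 ± 0.151, the melanosomal transporter OCA2 at 1.06 ± 0.168, the adhesion molecule L1CAM at -1.56 ± 0.307 and KIF26B at -1.17 ± 0.251 passed against PBS and without each array. The weaker arm lay under 11.7 in 3 lines for H3C8 and MAFF, 4 for L1CAM, 2 for KIF26B and 1 for OCA2, so the size of these changes depends on the floor. The other 14 were PYCR3, EDNRB-AS1, PLPP7, SERPINH1, SLC33A2 and CLCA4-AS1 among the rises and KIF12, ANKRD34A, CYP2C8, PRG2, FTCD, LINC01619, ALOX12 and TMEM125 among the falls. PRG2 changed by 0.18 against PBS.

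The combination against isotype asked what both antibodies did together. Lysosome and autophagy genes rose, 11 of 18 with 1 lower (11 and 1 adjusted over the list alone; adjusted p = 2.4e-05, or 0.019 with an estimated correlation). CTSA was at 0.40, the protease CTSS at 0.27 and TFEB at -0.24. Against PBS 9 were higher and 1 lower (adjusted p = 3.1e-08). Against isotype most of this rise came from HBL-2, with 11 higher and 0 lower (adjusted p = 4e-13). Each other line had 1 higher, and against isotype the list passed in none of them (adjusted p of 0.12 or more). Immediate early genes rose, 9 of 22 with 2 lower (9 and 2 adjusted over the list alone; adjusted p = 0.00063, or 0.012 with an estimated correlation). The AP-1 subunit FOS was at 1.52 ± 0.343, EGR1 at 0.94, EGR3 at 0.80, IER5 at -0.11 and MYC at -0.09. Against PBS 9 were higher and 1 lower, and MYC changed by 0.04. By line the list passed in Z138 and JEKO-1 alone (adjusted p = 0.037 and 2.9e-10). Heat shock genes rose, 5 of 9 and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.00063, or 0.034 with an estimated correlation), with BAG3 at 0.43 and HSPH1 at 0.41. Against PBS 2 were higher and the list did not pass (adjusted p = 0.41). G2/M genes were above isotype, 21 of 25 and 0 lower (24 and 0 adjusted over the list alone; adjusted p = 1.3e-24, or 1.7e-06 with an estimated correlation), with TPX2 at 0.40. Against PBS 1 was higher and 3 lower, with a median of -0.004 (adjusted p = 0.62). G1/S genes had 8 of 25 lower and 1 higher (9 and 2 adjusted over the list alone; adjusted p = 0.00063, or 0.051 with an estimated correlation). Against PBS 1 was lower and 0 higher (adjusted p = 0.5). The combination called 2411 genes, 1577 higher and 834 lower, with a split of 1271 and 1054 after quantile normalization. Of the 2411, 1307 had the same sign in all 5 lines. Against PBS 1184 were called, and 848 passed against both controls in the same direction. Of its 20 genes with the largest shared changes FOS, RNA45SN5 at 1.50 ± 0.0522, the G protein regulator RGS1 at 1.44 ± 0.163, MAFF at 1.38 ± 0.151, the growth factor HBEGF at 1.19 ± 0.123 and SYNE1 at 1.01 ± 0.258 passed against PBS and without each array. The weaker arm lay under 11.7 in 4 lines for FOS, 3 for MAFF and 1 each for RGS1, HBEGF and SYNE1. The other 14 were H3C8, BEND7, TUBBP5 and SLC33A2 among the rises and SPMIP1, LINC00951, NOTCH3, PLEKHA7, DDIT4L, WHRN, LOC100507395, KCNRG, RSPH1 and ABCB4 among the falls.

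GA101 was compared directly with rituximab to learn where the antibodies part. NF-kB targets were higher with GA101, 10 of 20 with 0 lower and 10 not called (11 and 1 adjusted over the list alone), and the list's median was 0.294 (adjusted p = 1.2e-27, or 4.7e-12 with an estimated correlation). CCL4 was higher by 0.83 ± 0.063, the BCL2 relative BCL2A1 by 0.58 ± 0.135 and the NF-kB brake TNFAIP3 by 0.41 ± 0.0551. Immediate early genes were higher too, 9 of 22 and 0 lower (11 and 1 adjusted over the list alone; adjusted p = 6.5e-18, or 2.6e-09 with an estimated correlation), with EGR3 at 0.84 ± 0.095, the early activation marker CD69 at 0.59 ± 0.0454 and EGR1 at 0.59. Chemokines, cytokines and their receptors were higher, 2 of 19 and 0 lower (2 and 0 adjusted over the list alone; adjusted p = 0.00023, or 0.0094 with an estimated correlation), with IL21R at 0.29. Heat shock genes were lower with GA101, 1 of 9 and 0 higher (3 and 0 adjusted over the list alone; adjusted p = 0.0031, or 0.061 with an estimated correlation), with HSPH1 at -0.11. Lysosome genes had 2 of 18 lower and 1 higher (3 and 2 adjusted over the list alone; adjusted p = 0.0065, or 0.14 with an estimated correlation), with PSAP at -0.19 and TFEB at 0.21. With the mean of a gene's probe sets the calls of HSPH1 and TFEB ended. By line, with the preset correlation, NF-kB targets passed upward in all 5, immediate early genes upward in 4 and downward in JEKO-1, and heat shock genes passed in JEKO-1 alone.

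In all 310 genes differed between GA101 and rituximab, 171 higher and 139 lower. Of the 20 with the largest shared changes, the platelet and leukocyte kinase substrate PLEK at 0.39 ± 0.0276, the EGR repressor NAB1 at 0.40 ± 0.0629, the non-coding MIR924HG at 1.26 ± 0.298 and LINC00158 at 0.92 ± 0.18 were higher, with CD69, BCL2A1 and TNFAIP3, and kept the call without each array; the weaker arm lay under 11.7 in 4 lines for MIR924HG and in 1 for LINC00158 and BCL2A1. KLHL24 at -0.40 ± 0.0505, EEIG1 at -0.43 ± 0.0952, PRXL2B at -0.43 ± 0.0955, ZNF594 at -0.34 ± 0.0829 and POMGNT1 at -0.29 ± 0.0716 were lower on the same terms, although KLHL24 and POMGNT1 lost the call with the mean of their probe sets. The other 8, DUSP13B, SGPP2, TLCD1, AVPR1A, SLC10A2, ZNF818P, NAPRT and CNPY4, lost the call without 1 or more arrays. Of the lists 10 passed, and 5 of these lost the call without single arrays. Left out in turn, arrays ended the call of B cell receptor signalling in 19 of 30 fits (adjusted p = 0.046, or 0.18 with an estimated correlation; 1 of 21 higher, 2 lower), of G2/M genes in 18 (0.046 and 0.36; 0 of 25 higher, 1 lower), of complement regulators and Fc receptors in 12 (0.04 and 0.061; 0 of 10 higher, 1 lower), of ER stress and ATF4 targets in 7 (0.039 and 0.14; 3 of 20 higher, 0 lower) and of cholesterol genes in 6 (0.039 and 0.16; 3 of 18 higher, 0 lower), which passed upward in Z138 and downward in HBL-2. The number of lists fell from 10 to 5 without Z138 GA101 replicate 2 or HBL-2 GA101 replicate 3, and to 6 without GRANTA-519 GA101 replicate 1, GRANTA-519 rituximab replicate 1, JEKO-1 rituximab replicate 2 or REC-1 GA101 replicate 1.

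**Figure D2:**
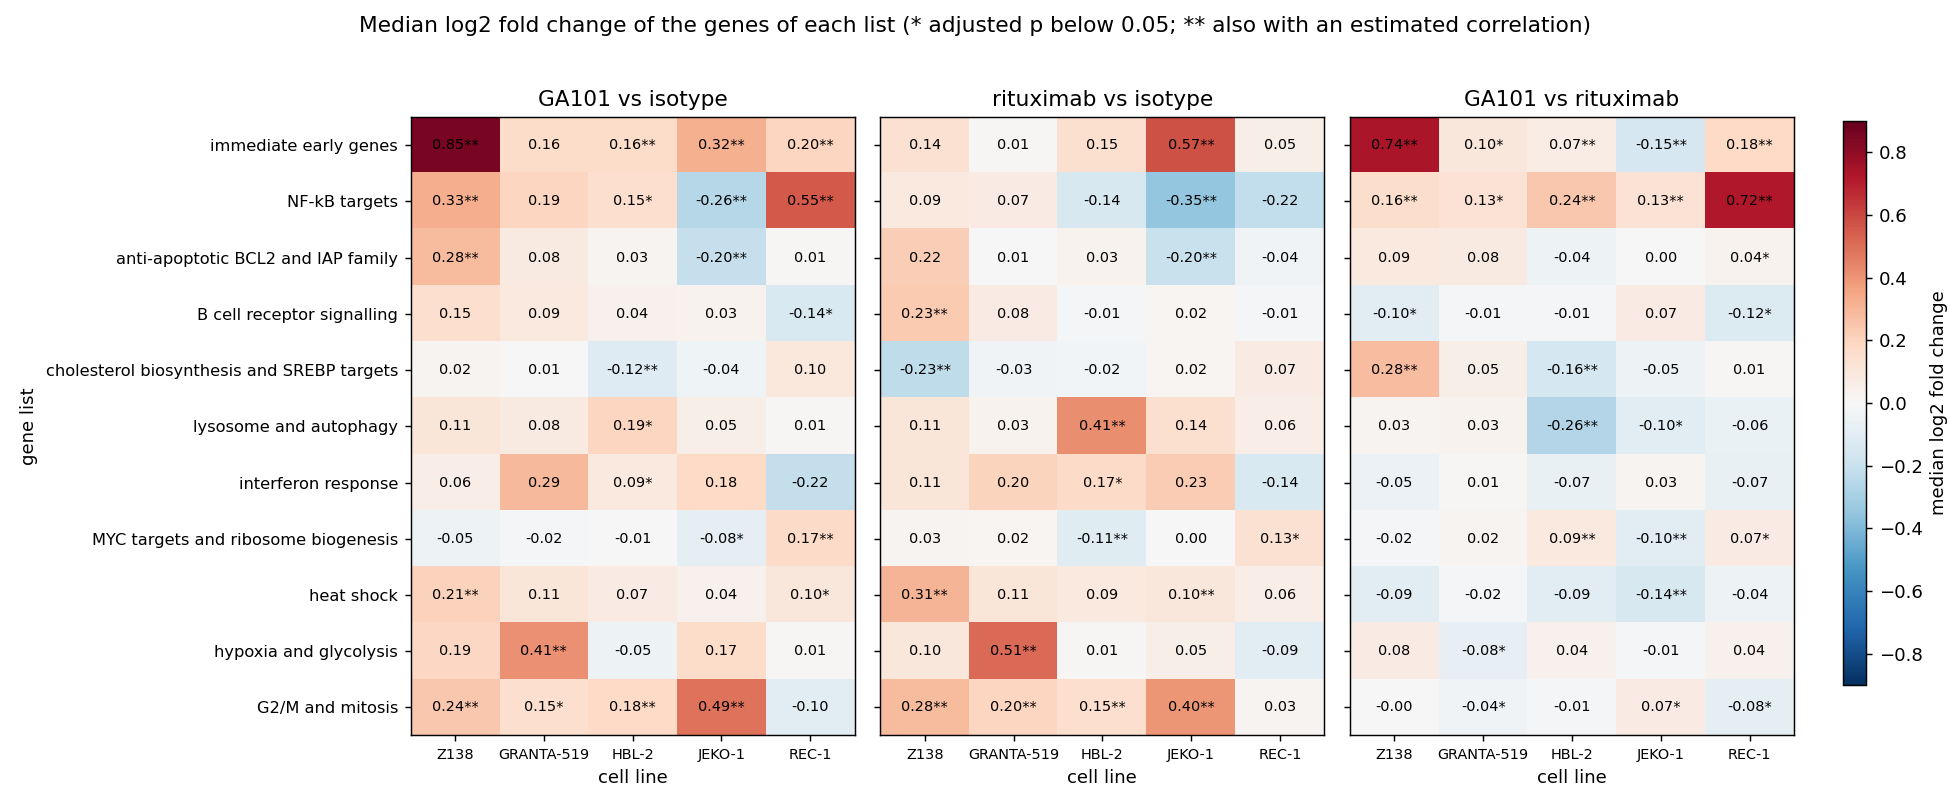
Median log2 fold change of selected gene lists (colour scale) in the 5 cell lines for GA101 against isotype, rituximab against isotype and GA101 against rituximab; 1 star marks a list past 0.05 with the preset correlation and a double star a list past it with an estimated correlation as well, and the lists drawn were selected after their values were seen. The NF-kB list reached 0.722 in REC-1 for GA101 against rituximab.

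Within single lines, 3 and 3 arrays that did not overlap made up between 10.2% and 27.4% of all genes, against 10% by chance. Many of the genes with the largest changes were dim: in the brighter arm their mean intensity was as low as 4.45, below the median probe set at 11.7. Of the 8 genes named per comparison, those are given here that also passed without each array and, where isotype was the control, against PBS. Of these 36 results 30 had a weaker arm with a mean intensity under 11.7, where the size of a change depends on the background and on the floor of 1, and in 5 every array of that arm was at or under the floor. A difference between lines needs the test given after the account of the lines.

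In Z138 GA101 raised immediate early genes, 15 of 22 with 1 lower (15 and 1 adjusted over the list alone; adjusted p = 4.8e-23, or 8.8e-11 with an estimated correlation). EGR1 rose by 3.18 ± 0.15, the orphan receptor NR4A3 by 3.46 ± 0.6 and the phosphatase DUSP2 by 2.35 ± 0.14, while ATF3 fell by 1.58. MAFF rose by 3.79 ± 0.338, and the myeloid nuclear antigen MNDA was listed at 0 with GA101 and at 6.01 with isotype. NF-kB targets rose, 7 of 20 and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 0.00011, or 0.0027 with an estimated correlation), with CCL4 at 2.12 ± 0.14 and NFKBIE at 0.65 ± 0.11. Anti-apoptotic genes rose too, 4 of 8 and 0 lower (4 and 0 adjusted over the list alone), with CFLAR at 0.55, BCL2 at 0.50 and MCL1 at 0.48 (adjusted p = 0.0045, or 0.016 with an estimated correlation). After rituximab Z138 had 8 of 21 B cell receptor signalling genes higher and 1 lower (11 and 2 adjusted over the list alone; adjusted p = 0.00037, or 0.019 with an estimated correlation). The kinase gene PIK3CD was at 0.82 ± 0.13, PLCG2 at 0.64 and PRKCB at 0.64, and MALT1 at -0.17. Cholesterol genes fell in Z138 after rituximab, 8 of 18 and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 3.4e-09, or 0.00036 with an estimated correlation), with INSIG1 at -0.71 ± 0.078, HMGCS1 at -0.57 and SQLE at -0.55. In the direct comparison GA101 exceeded rituximab for 8 of 18 cholesterol genes and 0 were lower (8 and 0 adjusted over the list alone; adjusted p = 2.3e-17, or 2.4e-07 with an estimated correlation), with STARD4 at 0.76 ± 0.066. It also exceeded it for 10 of 22 immediate early genes (16 and 1 adjusted over the list alone; adjusted p = 1.1e-38, or 1.1e-14 with an estimated correlation), with EGR1 at 2.86 ± 0.15 and EGR3 at 2.53 ± 0.21. It did so for CCL4 at 2.74 ± 0.142 and RASGEF1A at 3.22 ± 0.55. PRKAR1B-AS1 at -2.61 ± 0.538 and EMX1 at -2.59 ± 0.554 were lower, and CRIM1 was listed at 0 with GA101. Against PBS 13 immediate early genes, 5 NF-kB targets and 3 anti-apoptotic genes were higher after GA101, and 6 B cell receptor genes were higher and 6 cholesterol genes lower after rituximab. Changes of CFLAR at 0.33 and MCL1 at 0.26 after GA101, and of PLCG2 at 0.31, MALT1 at -0.07, INSIG1 at -0.44 and SQLE at -0.30 after rituximab, were smaller against PBS. The calls of NR4A3, BCL2, MCL1, PRKCB, SQLE and CRIM1 ended with the mean of the probe sets, and those of RASGEF1A, PRKAR1B-AS1, EMX1 and CRIM1 with a separate fit of the line.

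In Z138 1447 genes were called after GA101 (1189 higher, 258 lower; 683 and 368 after quantile normalization), 1745 after rituximab (1161 and 584; 1010 and 636) and 1452 after both (894 and 558; 838 and 567), with 526, 570 and 340 against PBS and 360, 443 and 253 in the same direction against both controls. GA101 and rituximab differed for 234 genes (199 and 35; 114 and 51 after quantile normalization) and the control arms for 297 (62 and 235; 63 and 179). Without GA101 replicate 1 the count for GA101 was 947 and that for GA101 against rituximab 142. Without isotype replicate 2 or PBS replicate 2 the count between control arms was 190 or 177.

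In GRANTA-519 the list with the smallest p after both antibodies was hypoxia and glycolysis. After GA101 6 of 18 members were higher and 0 lower (10 and 0 adjusted over the list alone; adjusted p = 3.2e-10, or 0.00019 with an estimated correlation), among them the vasodilator peptide gene ADM at 1.93 ± 0.23, the mTOR inhibitor DDIT4 at 1.75 ± 0.18 and ANKRD37 at 1.64 ± 0.15. After rituximab 11 were higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 1.1e-14, or 5.4e-06 with an estimated correlation), with ADM at 2.19 and DDIT4 at 1.81. Against PBS 0 and 1 of the 18 passed (adjusted p = 0.2 and 0.0013, or 0.11 with an estimated correlation for the latter), and the isotype arm itself lay below PBS by -1.57 for ADM and -1.55 for DDIT4. Of the largest changes TSPY26P at -2.75 ± 0.616 after rituximab held, and MEST at 2.47 ± 0.372 and PRXL2C at 2.05 ± 0.349 in GA101 against rituximab, the last pair not with a separate fit of the line. GA101 called 423 genes in GRANTA-519 (343 higher, 80 lower; 125 and 127 after quantile normalization), rituximab 584 (458 and 126; 195 and 182) and both 315 (254 and 61; 128 and 115), with 68, 185 and 52 against PBS and 28, 100 and 25 against both controls. GA101 and rituximab differed for 15 genes (7 and 8; 6 and 11 after quantile normalization) and the control arms for 114 (36 and 78; 48 and 62). Leaving out isotype replicate 2 gave 249, 385 and 203 genes for GA101, rituximab and both. Leaving out GA101 replicate 1 gave 210 for GA101, rituximab replicate 2 gave 372 for rituximab, combination replicate 2 gave 202 for both, and rituximab replicate 1 gave 23 for GA101 against rituximab.

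In HBL-2 rituximab raised lysosome and autophagy genes, 11 of 18 with 1 lower (12 and 1 adjusted over the list alone; adjusted p = 5.1e-11, or 0.00043 with an estimated correlation). CTSA rose by 1.16 ± 0.13, PSAP by 0.97 ± 0.062 and SQSTM1 by 0.80, and TFEB fell by 0.37. Against PBS 10 were higher and 1 lower. MYC targets and ribosome biogenesis genes fell after rituximab, 5 of 17 and 0 higher (5 and 0 adjusted over the list alone; adjusted p = 8.4e-06, or 0.02 with an estimated correlation), with the ribosome assembly factors RRS1 at -0.50 and NOP16 at -0.41. After GA101 cholesterol genes fell, 5 of 18 and 0 higher (8 and 1 adjusted over the list alone; adjusted p = 9.6e-07, or 0.0034 with an estimated correlation), with INSIG1 at -0.72 ± 0.078 and MSMO1 at -0.63. Immediate early genes rose, 4 of 22 with 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.0017, or 0.017 with an estimated correlation), with EGR3 at 2.05 ± 0.21, EGR1 at 1.64 ± 0.15 and IER5 at -0.27. Directly compared, GA101 lay below rituximab for lysosome genes (3 of 18 lower, 0 higher; 11 and 0 adjusted over the list alone; adjusted p = 1.5e-08, or 0.0028 with an estimated correlation), with PSAP at -0.67, and for cholesterol genes (3 of 18 lower, 0 higher; 6 and 0 adjusted over the list alone; adjusted p = 2.2e-06, or 0.003 with an estimated correlation). HBEGF rose by 3.31 ± 0.276 after GA101 and 4.30 ± 0.276 after rituximab, and RGS1 by 3.64 ± 0.363 after rituximab. SLC10A2 fell after GA101 from a mean intensity of 10.2 to 0.987 and the phosphatase gene PTPN13 from 9.33 to 0.66, and RILPL1 fell after rituximab from 13.9 to 1.35. In the direct comparison GPM6A was at 2.09 ± 0.308 and DTX3 at -2.86 ± 0.345, and SLC10A2 had 0.987 with GA101 and 9.44 with rituximab. Against PBS 5 MYC targets were lower after rituximab, 4 cholesterol genes were lower after GA101, and immediate early genes passed (adjusted p = 0.015) but not with an estimated correlation (adjusted p = 0.063), 3 higher and 1 lower, with EGR3 at 1.05 and EGR1 at 1.04. The calls of SQSTM1, PTPN13 and GPM6A ended with the mean of the probe sets.

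HBL-2 had 793 genes called after GA101 (408 higher, 385 lower; 474 and 401 after quantile normalization), 1360 after rituximab (873 and 487; 786 and 637) and 1171 after both (641 and 530; 715 and 521), with 594, 1032 and 1001 against PBS and 317, 706 and 637 against both controls. GA101 and rituximab differed for 252 genes (53 and 199; 93 and 153 after quantile normalization) and the control arms for 177 (47 and 130; 67 and 111). Without rituximab replicate 1 the former count was 153. Without isotype replicate 1, isotype replicate 2, PBS replicate 1 or PBS replicate 3 the latter was 81, 107, 108 or 103.

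In JEKO-1 NF-kB targets fell after both antibodies. After GA101 6 of 20 were lower and 2 higher (8 and 2 adjusted over the list alone; adjusted p = 0.00055, or 0.0072 with an estimated correlation), with the adhesion molecule ICAM1 at -0.83 ± 0.11, while CCL4 rose by 1.16. After rituximab 8 were lower and 2 higher (9 and 2 adjusted over the list alone; adjusted p = 7.9e-07, or 0.00015 with an estimated correlation), with NFKB1 at -1.03 ± 0.07 and RELB at -1.28, while CCL4 rose by 1.41. Immediate early genes rose in JEKO-1, 5 of 22 after GA101 and 12 after rituximab with 0 lower in either (6 and 0, and 14 and 1, adjusted over the list alone; adjusted p = 6.8e-06 and 9.8e-14; 0.00058 and 9.9e-08 with an estimated correlation). EGR3 rose by 2.74 and 2.87 and EGR1 by 1.60 and 1.87. Anti-apoptotic genes had 3 of 8 lower after GA101 and 4 after rituximab, with 0 higher in either (4 and 1 in both adjusted over the list alone; adjusted p = 0.0086 and 0.0027, or 0.026 and 0.0084 with an estimated correlation). After rituximab BCL2A1 was at -1.81 ± 0.3 and BCL2L1 at -1.35. After GA101 BCL2L1 was at -0.89, a call that ended in 5 fits without 1 array, and BCL2 at -0.42. The calls of BCL2L1 and of BCL2 ended with the mean of their probe sets. Against PBS 2 were lower after each antibody, and BCL2L1 changed by 0.03 after GA101 and -0.43 after rituximab. G2/M genes were higher than with isotype for 23 of 25 after GA101 (25 and 0 adjusted over the list alone; adjusted p = 4.2e-50, or 9.5e-11 with an estimated correlation), and 0 were higher or lower against PBS. Against PBS 5 and 7 NF-kB targets were lower after GA101 and rituximab, and 8 and 13 immediate early genes higher. In the direct comparison immediate early genes were lower with GA101, 2 of 22 with 0 higher (5 and 1 adjusted over the list alone; adjusted p = 5.5e-05, or 0.0035 with an estimated correlation), with MYC at -0.32. Mean intensity with rituximab and with isotype was 31.1 and 3.05 for MAFF, 21.2 and 2.05 for FOS, 25.3 and 3.03 for the surface receptor SLAMF7 and 0.683 and 10.9 for CORO2A. In GA101 against rituximab ARRDC3 was at 0.89 ± 0.146 and NAPRT at -2.52 ± 0.419. The calls of SLAMF7 with the mean of its probe sets, CORO2A with an offset before the logarithm and NAPRT with a separate fit of the line ended. JEKO-1 had 995 genes called after GA101 (752 higher, 243 lower; 477 and 356 after quantile normalization), 1038 after rituximab (625 and 413; 575 and 451) and 842 after both (619 and 223; 440 and 328), with 634, 549 and 534 against PBS and 298, 325 and 260 against both controls. GA101 and rituximab differed for 67 genes (41 and 26; 26 and 34 after quantile normalization) and the control arms for 283 (135 and 148; 116 and 180). Without isotype replicate 3 the counts for GA101 and both were 646 and 555, without GA101 replicate 1 that for GA101 against rituximab was 35. Without isotype replicate 1 that between control arms was 186.

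In REC-1 NF-kB targets rose after GA101, 9 of 20 with 1 lower (11 and 1 adjusted over the list alone; adjusted p = 1.6e-15, or 3.2e-08 with an estimated correlation). CCL4 rose by 2.42 ± 0.142, NFKBIE by 1.21 ± 0.11 and ICAM1 by 0.96 ± 0.11, while IRF1 fell by 0.61. Against PBS 11 were higher and 1 lower. Against rituximab 11 were higher and 0 lower (13 and 1 adjusted over the list alone; adjusted p = 1.7e-36, or 3.4e-14 with an estimated correlation), with ICAM1 at 1.18, NFKBIE at 1.11 and TNFAIP3 at 1.10. Immediate early genes rose after GA101, 5 of 22 and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 6.9e-05, or 0.0029 with an estimated correlation), with EGR3 at 1.15 and MYC at 0.68. MYC targets and ribosome biogenesis genes rose as well, 6 of 17 and 0 lower (7 and 0 adjusted over the list alone; adjusted p = 4.9e-08, or 0.0029 with an estimated correlation), with RRS1 at 0.45 and NOP16 at 0.40. After rituximab 5 of the latter were higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 9.9e-05, or 0.1 with an estimated correlation), and against PBS 3 (adjusted p = 0.025, or 0.48 with an estimated correlation). Of the genes with the largest changes CRYBA4 at 2.77 ± 0.505 rose after GA101 with CCL4, and KCNK1 at -2.83 ± 0.628, DNAJC3-DT at -2.51 ± 0.608 and GFI1B, a repressor of blood cell development, at -2.51 ± 0.465 fell. PSG5 fell by 2.65 after rituximab and was higher by 2.65 ± 0.53 in GA101 against rituximab, as was HCG26 by 3.06 ± 0.634. Against PBS 7 immediate early genes and 5 MYC targets were higher after GA101. Of 25 G2/M genes 15 were lower and 0 higher against PBS (median -0.254, adjusted p = 1e-13, or 2e-04 with an estimated correlation). The isotype arm itself had 5 lower and 0 higher than PBS. Against isotype 6 were lower and 2 higher after GA101 (adjusted p = 0.12). Against rituximab 6 were lower and 0 higher (adjusted p = 0.00037, or 0.063 with an estimated correlation). The calls of CRYBA4 and DNAJC3-DT ended with a separate fit of the line. REC-1 had 1618 genes called after GA101 (628 higher, 990 lower; 739 and 825 after quantile normalization), 717 after rituximab (431 and 286; 394 and 341) and 691 after both (409 and 282; 423 and 322), with 1324, 632 and 495 against PBS and 884, 334 and 263 against both controls. GA101 and rituximab differed for 434 genes (143 and 291; 210 and 202 after quantile normalization) and the control arms for 63 (35 and 28; 29 and 60). Without GA101 replicate 2, GA101 replicate 3 or rituximab replicate 1 the count for GA101 against rituximab was 206, 746 or 256, and without isotype replicate 3 that between control arms was 98.

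The response differed between lines by the F test for 1961 genes after GA101 and 1592 after rituximab, and for 1529 and 1228 with PBS as control. DUSP5, a nuclear phosphatase acting on ERK, had the largest F after GA101 (79, adjusted p = 3.5e-18): it changed by 2.20 ± 0.1 in Z138 and by -0.10 to 0.31 in the other lines. PNPLA8 (F = 70.3), RILPL2 (62.4), the ganglioside synthase ST3GAL5 (62.1) and the polysialyltransferase ST8SIA4 (61.2) followed. EGR1 differed between lines too (F = 55.6), from 3.18 in Z138 to 0.19 in GRANTA-519, and so did MAFF (F = 21.1) and RNA45SN5 (F = 14.9). After rituximab ST3GAL5 led (F = 146, adjusted p = 9.1e-25), with 1.80 ± 0.068 in HBL-2, followed by the sphingosine phosphate phosphatase SGPP1 (96.6), REPIN1 (94.3), ALDH5A1 (88.6) and the kinase STK17A (78.3). HBL-2 changed by 1.36 for SGPP1 and -0.98 for STK17A. MS4A1 differed as well (F = 9.19, adjusted p = 0.00028) and changed by 0.32 ± 0.053 in HBL-2. Over the NF-kB list, a list and pair of lines chosen after their values were seen, the median of the REC-1 minus JEKO-1 difference after GA101 was 0.75 (adjusted p = 2.3e-18, or 3.8e-09 with an estimated correlation).

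The combination was compared with each antibody to see whether it added to either. Against GA101 alone it lowered immediate early genes, 10 of 22 and 0 higher (12 and 0 adjusted over the list alone; adjusted p = 1.2e-18, or 1.4e-09 with an estimated correlation), with EGR3 at -0.79 and EGR1 at -0.55. It also lowered NF-kB targets, 9 of 20 and 0 higher (12 and 0 adjusted over the list alone; adjusted p = 1.3e-22, or 1.3e-10 with an estimated correlation), with CCL4 at -0.65 and NFKBIA at -0.35. Lysosome genes were higher, 1 of 18 and 0 lower (4 and 1 adjusted over the list alone; adjusted p = 5.9e-05, or 0.031 with an estimated correlation), with PSAP at 0.19. Chemokine genes had 2 of 19 lower (3 and 0 adjusted over the list alone; adjusted p = 0.0033, or 0.038 with an estimated correlation), and complement and Fc receptor genes passed as a list with 0 of 10 called (1 and 0 adjusted over the list alone; adjusted p = 0.041, or 0.04 with an estimated correlation). In all 199 genes differed, 84 higher and 115 lower (116 and 92 after quantile normalization). The smallest p belonged to PLEK at -0.37 ± 0.0276, ST3GAL5 at 0.34 ± 0.0303, SRSF5 at -0.25 ± 0.0233, CD69 at -0.49 ± 0.0454 and ZFP36L2 at 0.28 ± 0.0262, of which PLEK, SRSF5 and ZFP36L2 lost the call with the mean of their probe sets. Against rituximab alone limma called 0 genes, and 741 had an unadjusted p under 0.05; 1 gene passed without Z138 combination replicate 2 and 1 without HBL-2 combination replicate 3. Cholesterol genes were higher than with rituximab as a list (5 and 0 adjusted over the list alone; adjusted p = 3.9e-06, or 0.0053 with an estimated correlation) and heat shock genes lower (2 and 0 adjusted over the list alone; adjusted p = 0.038, or 0.24 with an estimated correlation).

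If the antibodies acted independently on the log2 scale, the combined change would equal the sum of the single ones. It departed from the sum for 1691 genes, 460 above and 1231 below (672 and 812 after quantile normalization; 735 genes with PBS as control, 557 shared in direction). EGR1 lay below the sum by -1.45 ± 0.0951, RNA45SN5 by -1.12 ± 0.0738, CHORDC1 by -0.98 ± 0.0436, PHF14 by -0.85 ± 0.0367 and HSPH1 by -0.50 ± 0.0303. With PBS as control the same genes were at -1.36, -1.27, -0.30, -0.14 and -0.28, so the departure of CHORDC1, PHF14 and HSPH1 came in good part from the isotype arm. By the mean of its probe sets PHF14 lay at 0.10. Immediate early genes were below the sum, 11 of 22 and 0 above (12 and 0 adjusted over the list alone; adjusted p = 5.1e-12, or 1e-06 with an estimated correlation), with EGR3 at -1.54, and with PBS as control 11 were below and 0 above (adjusted p = 4.3e-19, or 1.6e-09 with an estimated correlation). G2/M genes were below, 16 of 25 and 0 above (18 and 0 adjusted over the list alone; adjusted p = 1.1e-16, or 4.6e-05 with an estimated correlation), but with PBS as control 0 were below and 2 above (median 0.024, adjusted p = 0.2). Below the sum against isotype were also NF-kB targets, 5 of 20 with 1 above (7 and 1 adjusted over the list alone; adjusted p = 0.007, or 0.046 with an estimated correlation), with CCL4 at -1.16 and RELB at 0.27. Heat shock genes were below with 4 of 9, G1/S genes above with 6 of 25 and 1 below, GINS1 at -0.17, and cholesterol genes above with 4 of 18, each with adjusted p = 0.046 with an estimated correlation. The hypoxia list had 5 of 18 below and lost its call (adjusted p = 0.11 with an estimated correlation). With PBS as control the NF-kB, heat shock, G1/S, cholesterol and hypoxia lists did not pass (adjusted p = 0.095, 0.2, 0.22, 0.095 and 0.31). The isotype arrays enter this sum with the opposite sign to each antibody, so the shift between the control arms enters it too.

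For the 310 genes that differed between GA101 and rituximab the position of the combination was measured as a slope, where 0 equals rituximab and 1 equals GA101. It was 0.271 over all lines (jackknife SE 0.171; 0.235 to 0.363 without 1 array), and 82.9% of the genes lay nearer rituximab. Per line it was 0.38 in Z138 (234 genes; 0.249 to 0.519 without 1 array), 0.362 in GRANTA-519 (15 genes; 0.154 to 0.589), 0.247 in HBL-2 (252 genes; 0.176 to 0.462), 0.478 in JEKO-1 (67 genes; 0.347 to 0.769) and 0.316 in REC-1 (434 genes; 0.232 to 0.571). The jackknife SE was 0.23, 0.417, 0.299, 0.406 and 0.315 in these lines, so 0.5 lay within 2 SE of the slope over all lines and in each line.

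**Figure D3:**
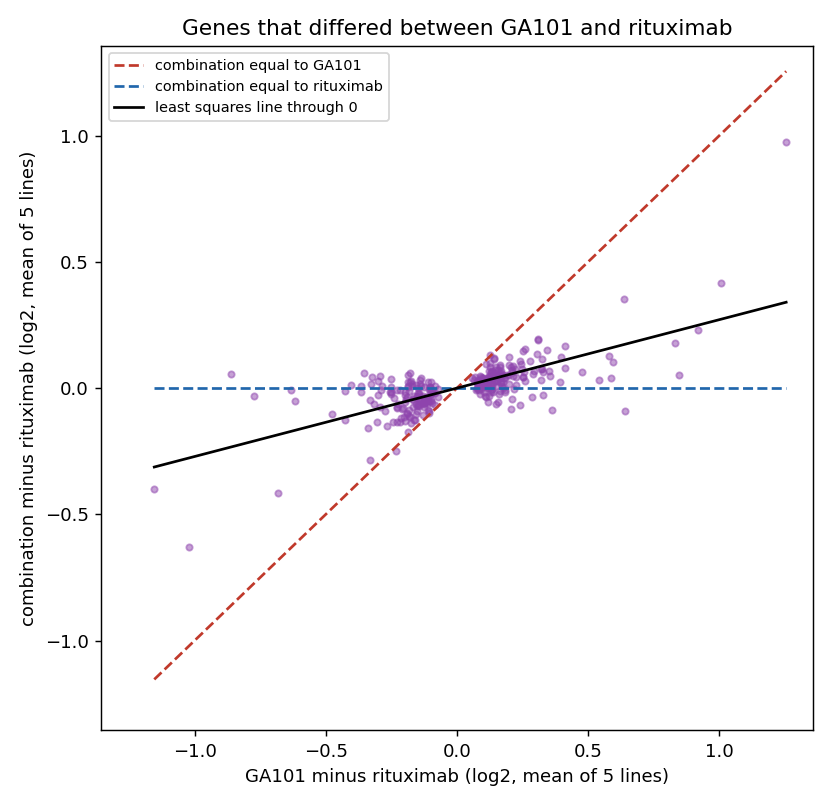
Combination minus rituximab against GA101 minus rituximab (log2 fold change over all lines) for the 310 genes that differed between GA101 and rituximab, 1 point per gene, with lines for a combination equal to GA101, a combination equal to rituximab and the slope of 0.271. Most points, 82.9%, lie nearer the rituximab line.

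The comparisons against isotype share control arrays, which alone makes fold changes correlate across genes. Over all lines GA101 and rituximab changes had r = 0.657 across 13870 genes, against 0.503 in 20 simulations with no effect or isotype shift. Covariance was 0.0301 against 0.015. The shift may cause the excess. Genes are not independent replicates. Of the called genes 1320 were higher in both, against 238 for independent lists, 531 lower in both, against 55.3, and 6 opposite. With isotype as control for GA101 and PBS for rituximab r was 0.255, with 692 higher and 243 lower in both. With the controls exchanged it was 0.208, with 575 and 222. GA101 and the combination had r = 0.644 (0.498 simulated, 0.22 and 0.197 with split controls, covariance 0.0284 and 0.0148). Rituximab and the combination had 0.681 (0.503, 0.242 and 0.267, 0.0315 and 0.0149).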

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

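Planned tests, such as the F tests and quantile normalization, and those of RNA degradation and dim NF-kB members were chosen before their results were seen. The others here, the splits of the arrays included, were chosen after. The genes and the NF-kB list given first stand out because their response differed between lines by the test of that difference. The rest is given for other reasons. Groups held 3 arrays, too few to look for single arrays far from the others.

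After GA101 1961 genes differed between lines. DUSP5 had F = 79, PNPLA8 70.3, RILPL2 62.4, ST3GAL5 62.1 and ST8SIA4 61.2. Of the genes named for shared changes, EGR1 (F = 55.6), MAFF (F = 21.1) and RNA45SN5 (F = 14.9) differed in size between lines. After rituximab 1592 genes differed. ST3GAL5 had F = 146, SGPP1 96.6, REPIN1 94.3, ALDH5A1 88.6 and STK17A 78.3. Of the genes named for shared changes RNA45SN5 (F = 28), MAFF (F = 13.9), OCA2 (F = 6.04) and PLPP7 (F = 4.51) differed in size, as did MS4A1 (F = 9.19). In 100 splits of the arrays the highest other count was 950 for GA101 and 1582 for rituximab, and 1 of 100 gave as many genes in each case, the real split. These splits exchange antibody and isotype arrays within each line, so they also remove the response that the lines share. They cannot tell a difference between lines from chance, and no conclusion is drawn from them for either antibody. For rituximab the margin was narrow as well, next to the range without 1 array, 1449 to 1644.

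After GA101 the NF-kB list rose in REC-1 and fell in JEKO-1, but CCL4 and CD83 rose in both. The median difference over the 20 genes was 0.75. In REC-1 10 were higher and 1 lower (ICAM1 by 1.79, NFKBIE by 1.53, NFKB1 by 1.33, CCL4 by 1.26 and IRF1 by -0.66). A shift of the isotype arms as the cause is argued against by the same difference against PBS, 0.97 (adjusted p = 4.6e-22, or 1.9e-10 with an estimated correlation). Dim probe sets stay open: of the 18 members past the stricter filter (median 0.79), some may pass in other lines only. Also open is a difference between the lines in NF-kB signalling after GA101. It may be biological, a hypothesis found and tested on the same data. Culture conditions that differ between lines were not tested.

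The isotype arrays stood apart from the PBS arrays in 896 genes over all lines. RNA degradation is argued against, since 972 genes were called with the 3' to 5' ratios of GAPDH and actin as covariates, 883 of them among the 896; the GAPDH ratio was 0.05 ± 0.04 with isotype and 0.06 ± 0.06 with PBS (SD, n = 15). Array scaling is argued against by 911 genes after quantile normalization. An effect of immunoglobulin as such is argued against by genes chosen in 4 lines and measured in the line left out, where the isotype arm shifted by 0.14 on average and the 3 antibody arms by -0.02 against PBS, although the GA101 arm of REC-1 shifted by 0.07 where its isotype arm shifted by 0.09. The isotype arm shifted the same way in 5 of 5 lines left out, so a handling batch of the isotype cultures and an effect of that 1 antibody cannot be told apart, because each line has 1 isotype arm and the labels give no batch.

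The combination lay nearer rituximab than GA101, with a position of 0.271 (jackknife SE 0.171), although 0.5 lies within 2 SE. Genes chosen and weighted on other replicates gave 0.193 (0.124 to 0.224 over folds, 82 to 189 genes). The stricter filter on dim probe sets gave 0.273. The spread leaves both the choice of genes on the same arrays and dim probe sets open as causes, and no biological one was tested. Within single lines the held-out position was 0.149 in Z138 and -0.051 in HBL-2, but 1.372, -8.851 and -1.097 in GRANTA-519, JEKO-1 and REC-1, where it was unstable.

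Each count over all lines was set against 100 splits of the arrays. The real split alone gave as many genes for GA101 (2529, highest other 412), rituximab (2866, 508) and the combination (2411, 216). The same held for GA101 against rituximab (310, 53), isotype against PBS (896, 102) and the combination against GA101 (199, 30). A chance assignment of arrays to these arms can be excluded, but not chance between cultures, since replicates may be technical. The departure from the sum gave 1691 genes, against at most 3 in other splits. Those splits exchanged arrays of all arms that enter the sum and so removed the single effects too. They therefore cannot tell a departure from chance. For the combination against rituximab the real count was 0, so 100 of 100 splits gave as many by necessity (highest 2), and the splits say nothing of that result.

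Within a line 3 against 3 arrays make 10 splits, too few for a share under 0.05, and the values are given only side by side. In Z138 the real counts 1447, 1745, 1452, 234 and 297, for GA101, rituximab and the combination against isotype, GA101 against rituximab and isotype against PBS, stood beside highest others of 24, 43, 63, 20 and 33. In GRANTA-519 423, 584, 315, 15 and 114 stood beside 25, 25, 33, 32 and 25, and 3 of 10 splits gave as many as the 15; in each other case in the 5 lines it was 1 of 10. In HBL-2 793, 1360, 1171, 252 and 177 stood beside 32, 25, 21, 13 and 37. In JEKO-1 995, 1038, 842, 67 and 283 stood beside 10, 8, 7, 7 and 14. In REC-1 1618, 717, 691, 434 and 63 stood beside 273, 30, 24, 58 and 26.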

How the results depend on the processing

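The stricter filter, PBS in place of isotype for the departure from the sum and the counts against both controls were chosen after the results were seen; the other alternatives were planned. Of the named genes in their comparisons, 611 kept their direction and side of the threshold with a replicate block, 579 with quantile normalization, 569 with no filter, 452 with the mean of probe sets, 535 with separate fits or weights per line, 591 with an offset, 234 against PBS and 490 with the stricter filter, under which dropped genes have no value; 7, 40, 53, 160, 87, 29 and 204 lost the call in the first 7 of these. Of the lists 90, 87, 90, 85, 92, 90 and 55 kept theirs in the first 7, 77 with an estimated correlation and 76 with the stricter filter. Replicate numbers were not taken to pair the arrays, since 1 of 150 pairs of arrays of 1 line with the same number had a residual r over 0.1 (mean 0.028, -0.081 to 0.12). A weak shared deviation was visible all the same: 56 of 75 arrays correlated best with their own number (14, 14, 13, 12 and 3 of 15 in Z138, GRANTA-519, HBL-2, JEKO-1 and REC-1; mean r with other numbers -0.014), and replicate 3 had the highest phe control signal in 22 of 25 groups. Signal over background limits dim genes: the filter level, 11.7, lies among the median intensities of single arrays, 11.06 to 17.42.

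For the values that reversed or counts that moved by over 1.5 times the cause was not tested. Against PBS these reversed: the G2/M median to -0.017 after GA101, -0.012 after rituximab and -0.004 after both. Over all lines after GA101 SPMIP1 went to 0.37, RIMS4 to 0.03, MCL1 to -0.03, CENPF to -0.01 and CENPE to -0.08. After rituximab PRG2 went to 0.18, CFLAR to -0.09, CDC6 to 0.03 and CENPE to -0.04. After both MYC went to 0.04, CFLAR to -0.09, HMMR to -0.01, TRIB3 to 0.03 and HSPA4L to -0.06. In single lines HOXD4 went to -0.23, KLHL35 to -0.55 and BCL2L1 to 0.03 (JEKO-1, GA101), CENPE to -0.07 (JEKO-1, rituximab), HMMR to -0.04 (Z138, GA101), CDT1 to 0.05 and HMMR to -0.02 (Z138, rituximab) and AURKA to -0.10 (GRANTA-519, GA101). With the mean of probe sets PHF14 went to 0.03 for isotype against PBS and 0.10 for the departure from the sum, NPC1 to -0.02 after GA101 and -0.13 after both, LSS to -0.01 after rituximab and -0.02 after both, BLK to 0.29 after both, BUB1 to -0.17 (HBL-2, GA101) and BCL2 to 0.02 (JEKO-1, rituximab). SCML1 (HBL-2, rituximab) went to -0.34 with the offset and -0.58 with the stricter filter, and ARMCX5 (REC-1, GA101 against rituximab) to 0.08 with the latter.

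The number of lists called after GA101 was 4 against PBS, 4 with an estimated correlation and 5 with the stricter filter; after rituximab 3 with an estimated correlation; after both 3 against PBS; and for GA101 against rituximab 6 with the mean of probe sets, 3 with an estimated correlation and 5 with the stricter filter. Counts of genes follow in the order GA101, rituximab, both, GA101 against rituximab, and isotype against PBS. The mean of probe sets gave 807, 1008, 814, 125 and 174 in Z138, 433, 851, 738, 164 and 87 in HBL-2, 560, 578, 457, 43 and 150 in JEKO-1, 969, 357, 337, 211 and 22 in REC-1, and 310 and 166 for rituximab and both in GRANTA-519. Over all lines it gave 1602 for both, 174 for GA101 against rituximab, 489 between controls, 110 for both against GA101, 937 for the departure from the sum, and 1106 and 915 between lines for GA101 and rituximab. PBS gave, for the first 3, 526, 570 and 340 in Z138, 68, 185 and 52 in GRANTA-519, 634, 549 and 534 in JEKO-1 and 1469, 1682 and 1184 over all lines, and 735 for the departure from the sum. Separate fits gave, for the last 2, 107 and 108 in Z138, 27 and 158 in JEKO-1 and 240 and 11 in REC-1, 184, 350, 112, 1 and 17 in GRANTA-519 and 86 between controls in HBL-2. Quantile normalization gave 252 and 377 in GRANTA-519 for GA101 and rituximab. The replicate block gave 494 for both and 25 for GA101 against rituximab in GRANTA-519 and 144 between controls in REC-1. For GA101 against rituximab in GRANTA-519 the offset gave 4 and the stricter filter 5. For both against rituximab, 0 in the reported fit, quantile normalization gave 1 and the block 2.

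Without 1 array the ranges of results that moved were, for lists in GA101 against rituximab, 5 to 10, and for both against rituximab 0 to 1. For GA101 they were 947 to 1247 in Z138, 210 to 352 in GRANTA-519 and 646 to 937 in JEKO-1; for rituximab 372 to 528 in GRANTA-519; and for both 202 to 283 in GRANTA-519 and 555 to 749 in JEKO-1. For GA101 against rituximab they were 142 to 224 in Z138, 15 to 23 in GRANTA-519, 153 to 239 in HBL-2, 35 to 63 in JEKO-1 and 206 to 746 in REC-1. Between controls they were 177 to 235 in Z138, 81 to 197 in HBL-2, 186 to 255 in JEKO-1 and 59 to 98 in REC-1.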

Other observations

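Other lists moved within single lines, and those given here were chosen after their values were seen. In Z138 rituximab raised heat shock genes, 4 of 9 and 0 lower (7 and 0 adjusted over the list alone; adjusted p = 3.2e-05, or 0.0084 with an estimated correlation), with HSPH1 at 0.65 ± 0.048 and DNAJB1 at 0.46 ± 0.078; 2 were higher and 0 lower against PBS (adjusted p = 3e-04). Fc receptor and complement genes rose there as well, 4 of 10 and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.013, or 0.019 with an estimated correlation), with the inhibitory Fc receptor FCGR2B at 0.33 ± 0.076 and FCRLA at 0.37 ± 0.087. Against PBS the list did not pass (adjusted p = 0.11). Actin cytoskeleton genes had 5 of 20 higher and 0 lower (6 and 0 adjusted over the list alone), with the leukocyte GTPase RAC2 at 0.71 ± 0.069 and CORO1A at 0.57 ± 0.09 (adjusted p = 0.0064, or 0.1 with an estimated correlation). Against PBS 4 were higher and 0 lower (adjusted p = 4.3e-05). In JEKO-1 rituximab raised heat shock genes, 4 of 9 and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 2.1e-06, or 0.0021 with an estimated correlation), with HSPH1 at 0.70 ± 0.048 and BAG3 at 0.75 ± 0.16; 3 were higher and 0 lower against PBS (adjusted p = 0.0014).

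In HBL-2 interferon response genes had 4 of 20 higher and 0 lower after rituximab (4 and 0 adjusted over the list alone; adjusted p = 0.025, or 0.11 with an estimated correlation), and among them were the antiviral synthetases OAS1 at 2.49 ± 0.18 and OAS2 at 1.47 ± 0.24. Against PBS 4 were higher and 0 lower, and these were at 2.37 and 1.70. OAS1 was lower with GA101 than with rituximab by -1.07 ± 0.18. HBL-2 isotype arrays had 5 of 20 NF-kB targets lower than PBS and 0 higher (8 and 0 adjusted over the list alone; adjusted p = 2.3e-10, or 4.4e-06 with an estimated correlation). The same list after GA101 in HBL-2 had 3 higher and 0 lower against isotype (3 and 0 adjusted over the list alone; adjusted p = 0.017, or 0.063 with an estimated correlation), and 0 higher and 3 lower against PBS (adjusted p = 0.045, or 0.11 with an estimated correlation). In REC-1 GA101 exceeded rituximab for ER stress and ATF4 targets, 3 of 20 and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.0012, or 0.022 with an estimated correlation), with HERPUD1 at 0.49 ± 0.045 and the chaperone HSPA5 at 0.19 ± 0.033.

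fry, which asks whether the genes of a list move on balance and not whether they move more than others, gave p = 2e-27 for immediate early genes, 5.5e-17 for NF-kB targets and 1.8e-21 for G2/M genes after GA101 over all lines. For GA101 against rituximab it gave 2.3e-16, 1.1e-20 and 0.083. Of markers of other cell types that were tested, the highest mean intensity in any line was 428 for CD28, 203 for LCK, 86.4 for LYZ, 68.7 for CD3G, 64.4 for COL1A1, 38.5 for KRT8 and 36.8 for HBB. Several other markers did not pass the filter, and intensities of different probe sets cannot be ranked, so these values do not measure a share of other cells.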
